A study of Homo sapiens with 18 samples.

How the data were processed

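Gene expression was measured with Affymetrix Clariom S human arrays in the Fa2N-4 hepatocyte line, in single culture or in indirect co-culture with human monocyte derived macrophages (15% or 50%) for 24 h or 48 h. Each of the 6 groups had 3 arrays, stated in the labels as biological replicates. The deposited table held log2 expression values for 24351 probe sets on 18 arrays, made by the authors with Affymetrix Expression Console and Transcriptome Analysis Console, per the submitters' processing notes. The summarisation algorithm and the normalisation within those programs are not given in the sources used here. The values were used as deposited, and their array medians and negative controls fitted a log2 scale.

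The 2903 control probe sets were set aside, which left 21448 transcript clusters, all of them tested. Symbols were taken from the platform annotation and matched to a reference table of current names: 17709 clusters had 1 symbol and 3739 were not named here. A symbol with several clusters (20 symbols) was represented by the cluster with the highest mean. Background was set on each array at the 95th percentile of its 612 negative control probe sets, and lay between 7.54 and 8.73 on the log2 scale. It was used to describe signals and not to filter: 11530 clusters were above it on no array. Some genes chosen as reference points are not reported here.

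Differences were tested with limma (lmFit, contrasts.fit and eBayes) on 6 group means over 18 arrays, with 12 residual degrees of freedom, 2-sided, and Benjamini-Hochberg adjustment over all clusters at 0.05. Each co-culture was compared with the single culture of its time, 50% with 15% co-culture at each time, and 48 h with 24 h in single culture. The differences of the co-culture effects between times and the mean effect of 50% co-culture over both times were further contrasts. Errors printed with log2 differences are limma's moderated standard errors, and the SD is given for group means. Gene lists with at least 5 measured members (36 of 37 lists, 679 of 787 genes measured) were tested with camera at its preset correlation of 0.01, with adjustment over the lists. Camera compares the genes of a list with all other genes. Fry, an alternative that asks whether the genes of a list move on balance one way without comparing them with other genes, called 0 lists in each of the 4 comparisons with single culture, as camera with a correlation estimated per list did. A median log2 change of a list is the median over its measured members.

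The comparisons, tests, gene lists and most alternatives were chosen before the data were examined, as was the rule for the genes named. For each co-culture against single culture, the rule took the 8 largest rises and the 8 largest falls among genes that passed with all 3 co-culture arrays beyond all 3 single culture arrays. As none passed, it gave the reference genes (IL6, IL1B, CXCL8, CCL2, NFKBIA, SOCS3, CRP, SAA1, ALB, CYP3A4, CYP1A2 and NR1I3) and the 1 or 2 members of each list with the largest absolute change. Genes outside the rule are said to have been chosen after their values were seen. XIST and Y-linked genes were left out because the cells were exposed to donor macrophages. No fold is given where a group lay below background on all of its arrays.

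The alternatives were quantile normalisation of the 18 arrays, a filter that removed the dimmest 30% of clusters (15013 kept), eBayes with a trend and robust prior, a fit on the arrays compared only, a fold threshold of 2, the mean of a symbol's clusters, each array left out in turn, a block for runs of 6 consecutive sample numbers, a correlation estimated per list, and fry. Fits without replicate 3 of 15% co-culture at 24 h, the block together with that omission or with an estimated correlation, and the omission of each array for the lists of the other 6 comparisons and for genes adjusted over the list alone were added after seeing the data. The procedure was tested on data simulated for 50% co-culture against single culture at 24 h over 21448 clusters. In 5 simulations it recovered 8.06% of genes changed 1.5-fold, 50.8% of those changed 2-fold and 97.6% of those changed 4-fold, with 27 false calls. Each simulation held 200 changed genes besides a shifted list, which loosens the Benjamini-Hochberg threshold. The shares recovered therefore do not hold for a comparison with few changed genes, where smaller shares would be found. A list shifted by 0.5 log2 units was called 5 of 5 times, at the preset and at an estimated correlation. The simulated genes varied independently, without correlation within lists or shared deviations of arrays. The simulations therefore do not show how the list test behaves where genes of a list vary together. R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.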

Results

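RNA was measured on 18 microarrays from Fa2N-4 cells, a human hepatocyte line immortalised with SV-40. The cells were grown alone (single culture) or below inserts that held human monocyte derived macrophages, so that the cell types shared medium without touching. The inserts were labelled as 15% or 50% macrophages, and RNA of the hepatocyte line was collected at 24 h or 48 h, which gave 6 groups of 3 arrays. The arrays covered 21448 transcript clusters, of which 17709 carried 1 gene symbol. The median log2 value per array lay between 6.72 and 6.82. Between 7379 and 9155 clusters per array (34.4% to 42.7%) were above background. The number of arrays limits the precision: the median 95% interval of a difference between groups reached 0.47 log2 units to either side, a factor of 1.39.

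Replicate 3 of 15% co-culture at 24 h stood apart from the other arrays. Its correlations with them across clusters were 0.972 to 0.978, against 0.987 to 0.996 for the 136 pairs without it. The typical size of its residuals was 0.46 log2 units, against 0.20 to 0.32 in the other 17 arrays. Hypoxia response genes, the targets switched on when oxygen is low, also spread most in its group. Their level relative to the mean of all 18 arrays was 0.02 ± 1.05 (SD, n = 3) in 15% co-culture at 24 h, against -0.43 ± 0.33 (SD, n = 3) in single culture and 0.34 ± 0.52 (SD, n = 3) in 50% co-culture at that time.

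**Figure D1:**
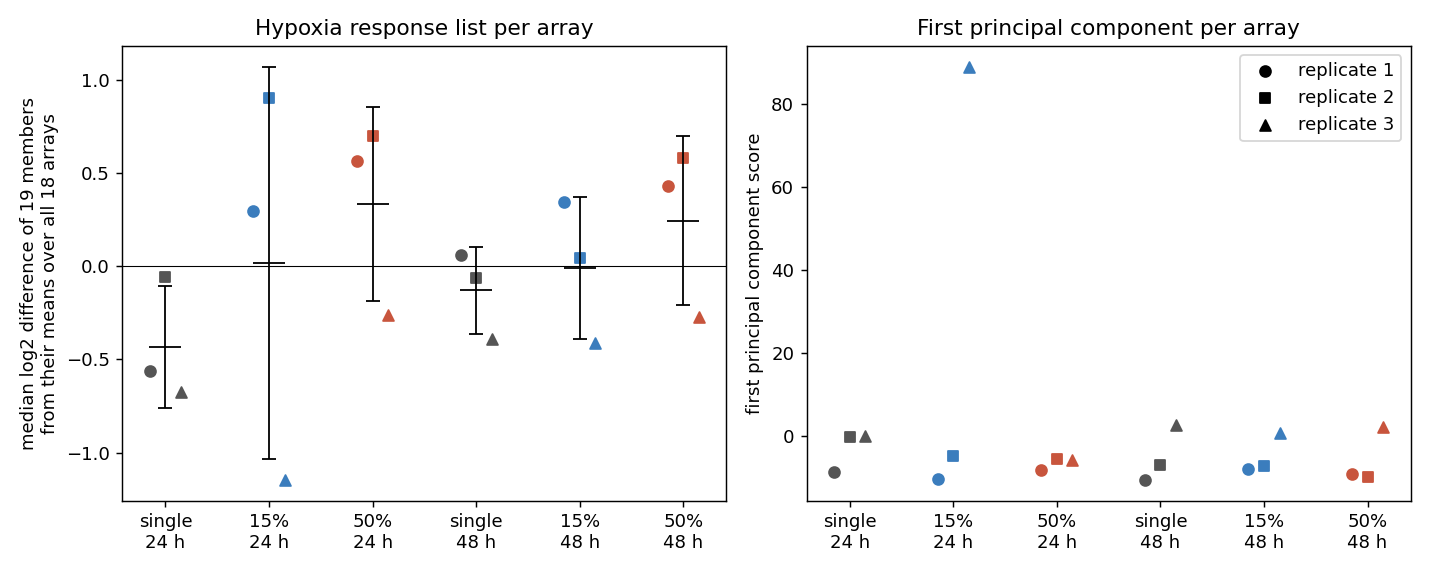
The left panel plots the level of the hypoxia response list on each of the 18 arrays (log2 units, the median difference of its 19 members from their means over all arrays), with bars for the group mean ± SD, and the right panel plots the score of each array on the first principal component (22.8% of the variance). Replicate 3 of 15% co-culture at 24 h lies far from the other 17 arrays in the right panel, whose scores run from -10.6 to 2.64.

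The comparison of 50% co-culture with single culture at 24 h asked how the hepatocyte line differed when it shared medium with macrophages it did not touch. Signals from the macrophages were not measured. IL6, the cytokine that drives the hepatic acute phase response, had a log2 signal of 10.54 ± 0.27 (SD, n = 3) in co-culture and 9.76 ± 0.74 (SD, n = 3) alone, 1.72-fold higher. The neutrophil chemokine CXCL5 was 2.72-fold higher (log2 difference 1.44 ± 0.40, SE, n = 3 per group), and the adhesion molecule ICAM1 1.68-fold higher (0.74 ± 0.30). CCL5, a chemokine for T cells and monocytes, was 3.34-fold lower (-1.74 ± 0.69). Without single culture replicate 1 the IL6 difference was 0.44, and without replicate 2 that of CCL5 was -1.08. No single gene passed the test: limma called 0 of 21448 clusters (smallest adjusted p = 0.9999), with 531 at an unadjusted p under 0.05. By chance 1072 would be expected if the arrays varied independently. Arrays with neighbouring sample numbers deviated together, as described below, and the fit did not include this. The low count of 531 therefore does not show an absence of change. The count of genes that passed adjusted over the list alone was 0 as well.

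Gene lists moved together in this comparison, by camera with a preset correlation of 0.01. All 19 measured hypoxia response genes were higher, with a median log2 change of 0.84 (adjusted p = 6.92e-13, but adjusted p = 0.309 with an estimated correlation). Among them PDK1, which keeps pyruvate out of the mitochondria, was 1.26 ± 0.58 log2 units higher, and NDRG1 was above background on 2 co-culture arrays and on 0 single culture arrays. Acute phase proteins were higher for 15 of 19 members (median 0.42, adjusted p = 3.25e-05), among them CP, which carries copper in plasma (1.91 ± 0.82, above background on 2 co-culture arrays and on 1 alone). SAA1, a main acute phase protein, was 2.98-fold higher (1.57 ± 0.94). Cytokines and chemokines were higher for 21 of 30 members (median 0.21, adjusted p = 0.000172) and NF-kappaB target genes for 17 of 21 (median 0.25, adjusted p = 0.000252). These 3 inflammatory lists each had adjusted p = 0.309 with an estimated correlation. Type I interferon response genes, which act against viruses, were lower for 35 of 36 members (median -0.38, adjusted p = 3.79e-06, and adjusted p = 0.595 with an estimated correlation). Within that list IFIH1, a sensor of viral RNA, differed by -0.84 ± 0.47 and IFIT1, which blocks translation of viral RNA, by -0.83 ± 0.45.

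A further 5 lists passed as higher by smaller steps. Lipogenesis had a median of 0.20 (adjusted p = 0.00528), with FASN, the fatty acid synthase, at 0.37 ± 0.36. The interferon-gamma response had a median of 0.16 (adjusted p = 0.00649), with CD74, the chain that guides antigen loading, at 0.71 ± 0.37. Cholesterol synthesis had a median of 0.20 (adjusted p = 0.00649), complement components 0.09 (adjusted p = 0.0111) and ribosomal proteins 0.14 (adjusted p = 0.0167). C1R, which starts the classical complement cascade, differed by 1.38 ± 0.62, and CFB, of the alternative pathway, by 1.25 ± 0.51. Metallothioneins, which bind zinc and copper, were lower for 9 of 11 members (median -0.35, adjusted p = 0.0167), and immediate early genes for 12 of 17 (median -0.26, adjusted p = 0.0236). With an estimated correlation these 7 lists had adjusted p between 0.309 and 0.602, so that none of the 12 lists passed with it. Medians without 1 array were as small as 0.0095 for complement components (without 50% replicate 2), 0.02 for ribosomal proteins and 0.09 for cholesterol synthesis (both without single culture replicate 2), and 0.08 for the interferon-gamma response and -0.09 for metallothioneins (both without single culture replicate 1). They reached 0.24 for complement components (without 50% replicate 3), 0.30 for cholesterol synthesis (without 50% replicate 2), and 0.31 and 0.21 for the interferon-gamma response and ribosomal proteins (without single culture replicates 2 and 1). Leaving out 1 array ended between 2 and 6 of the 12 calls, with adjusted p up to 0.365 without 50% replicate 1, 0.259 without 50% replicate 2, 0.505 without 50% replicate 3, and 0.592, 0.521 and 0.367 without single culture replicates 1, 2 and 3. The hypoxia, acute phase, cytokine and NF-kappaB lists passed without each of the 6 arrays, although the acute phase median was 0.81 without 50% replicate 3, the cytokine median 0.13 without 50% replicate 1 and 0.35 without single culture replicate 2, and the interferon median -0.18, -0.73 and -0.11 without 50% replicate 1 and single culture replicates 1 and 2.

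**Figure D2:**
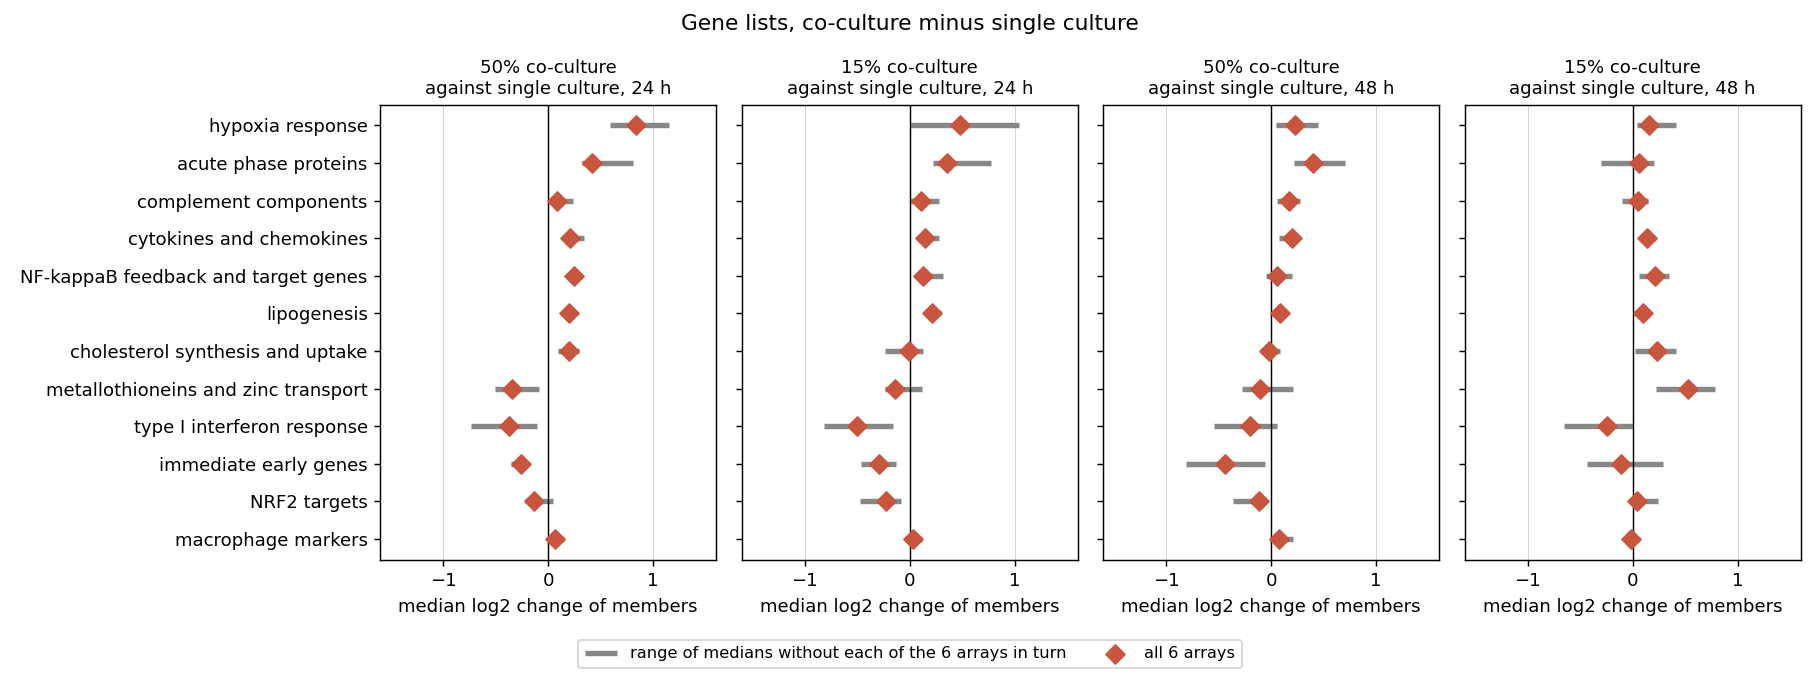
Red diamonds give the median log2 change of the members of 12 gene lists between a co-culture and the single culture of the same time, in 1 panel per comparison, and grey bars give the range of that median when each of the 6 arrays was left out in turn. At 24 h in 50% co-culture the hypoxia median of 0.84 ranged from 0.59 to 1.15, while the type I interferon median of -0.38 ranged from -0.73 to -0.11.

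In 15% co-culture at 24 h, a smaller share of macrophages was compared with the same single cultures. All 36 type I interferon response genes were lower (median -0.50, adjusted p = 9.67e-07, and adjusted p = 0.769 with an estimated correlation). MX1, which traps viral nucleoproteins, was 1.95-fold lower (-0.97 ± 0.44, SE, n = 3 per group), and CCL5 was 3.71-fold lower (-1.89 ± 0.69). Hypoxia response genes were higher for 15 of 19 members (median 0.48, adjusted p = 0.00337, and adjusted p = 0.769 with an estimated correlation). Acute phase proteins were higher for 17 of 19 (median 0.35, adjusted p = 0.0165, and adjusted p = 0.66 with an estimated correlation), with CP at 1.55 ± 0.82 and SAA1 at 0.49 ± 0.94. IL6 differed by 0.44 ± 0.34 and ICAM1 by 0.69 ± 0.30. Limma called 0 clusters (smallest adjusted p = 0.185), with 1195 at an unadjusted p under 0.05, and 1 gene adjusted over the list alone, the complement component C9, which lay below background on every array and passed only without 15% replicate 3 when each of the 6 arrays was left out in turn (adjusted p without the others from 0.0625 to 0.242).

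The camera test called 8 lists in this comparison and 0 with an estimated correlation. The other 5 were smaller in median: coagulation factors at 0.26, lipogenesis at 0.22 and cytokines at 0.14 were higher, and NRF2 targets at -0.22 were lower (adjusted p = 0.0415 for each). Immediate early genes were lower for 15 of 17 members (median -0.29, adjusted p = 0.0343), with the stress regulator ATF3 at -0.63 ± 0.55. With an estimated correlation these 5 lists had adjusted p between 0.66 and 0.769. SCD, which desaturates fatty acids, differed by 0.55 ± 0.20, F3, the tissue factor that starts clotting, by 0.47 ± 0.24, and TALDO1, of the pentose phosphate pathway, by -0.68 ± 0.44. The hypoxia median was 0.31 without 15% replicate 1 (adjusted p = 0.138), 0.0045 without 15% replicate 2 (0.992), 1.05 without 15% replicate 3, and 0.31 without single culture replicate 3 (0.0712). The interferon median was -0.26 without 15% replicate 1 (0.115), -0.81 without single culture replicate 1 and -0.16 without replicate 2 (0.0731). The acute phase median ranged from 0.22 without single culture replicate 3 to 0.78 without 15% replicate 3, that of NRF2 targets from -0.47 without 15% replicate 1 to -0.09 without 15% replicate 3, and that of immediate early genes from -0.46 without 15% replicate 2 to -0.13 without single culture replicate 1. Coagulation factors had a median of 0.03 without single culture replicate 1, and cytokines of 0.28 without replicate 2. Calls of these lists and of lipogenesis ended without 15% replicates 1, 2 or 3 (adjusted p up to 0.394, 0.504 and 0.695) or without single culture replicates 1, 2 or 3 (up to 0.786, 0.267 and 0.2), while 5 ended after quantile normalisation (from 0.0507 to 0.108) and 4 without the dimmest 30% of clusters (from 0.0621 to 0.131).

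After 48 h in 50% co-culture, the comparison with single culture of that age asked how the line differed after the longer exposure. IL6 was 2-fold higher, with a log2 signal of 11.31 ± 0.41 (SD, n = 3) against 10.31 ± 0.60 (SD, n = 3), a log2 difference of 1.00 ± 0.34 that was 0.66 without single culture replicate 1. CPS1, the first enzyme of the urea cycle, was 3.42-fold higher (1.77 ± 0.54, SE, n = 3 per group), ICAM1 differed by 0.83 ± 0.30, and TGFBI, a matrix protein induced by TGF-beta, by 1.06 ± 0.36. Acute phase proteins were higher for 16 of 19 members (median 0.40, adjusted p = 0.000901), and immediate early genes were lower for 16 of 17 (median -0.44, adjusted p = 1.72e-05). Each of the 7 lists that passed had adjusted p = 0.893 with an estimated correlation. CP differed by 1.89 ± 0.82, SAA1 by 1.07 ± 0.94, and EGR1, an early growth response factor, by -1.28 ± 0.56, being above background on 1 co-culture array and on 3 alone. KLF2, an anti-inflammatory transcription factor, was above background on 0 co-culture arrays and on 2 single culture arrays, and was the 1 gene that passed adjusted over the list alone (adjusted p = 0.00397, limma), as it did without each of the 6 arrays. Over all genes limma called 0 clusters (smallest adjusted p = 0.26), with 616 at an unadjusted p under 0.05. A block for runs of 6 consecutive sample numbers, which the labels do not state as a pairing, gave 2.

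Hypoxia response genes were higher at 48 h for 15 of 19 members (median 0.22, adjusted p = 0.0333), but their median was 0.05 without 50% replicate 2 (adjusted p = 0.683), 0.12 without 50% replicate 1 (0.225), 0.07 without single culture replicate 3 (0.432) and 0.45 without 50% replicate 3. With an estimated correlation the 5 lists of this paragraph, like the others at 48 h in 50% co-culture, had adjusted p = 0.893. Among the hypoxia genes was PGK1, a glycolytic enzyme, at 0.97 ± 0.54. Cell cycle genes were higher for 24 of 32 (median 0.10), NRF2 targets lower for 15 of 17 (median -0.12) and p53 targets lower for 11 of 16 (median -0.19), each with adjusted p = 0.0333. The kinase PLK1, which drives mitosis, differed by 0.32 ± 0.19 and GADD45A, a p53 target that slows division, by -0.67 ± 0.40. Type I interferon response genes were lower for 27 of 36 (median -0.20, adjusted p = 0.0411). Their median was 0.03 without 50% replicate 1 (adjusted p = 0.912), 0.06 without single culture replicate 2 (0.847) and -0.03 without single culture replicate 3, with the test then pointing up (0.976), and it did not pass without 15% replicate 3 of 24 h (0.0562). The acute phase median was 0.22 without 50% replicate 1 (adjusted p = 0.147), 0.71 without single culture replicate 2 and 0.26 without replicate 3 (0.14), that of immediate early genes -0.06 without single culture replicate 1 (0.739). Calls of the other 4 lists ended without 50% replicates 1, 2 or 3 (up to 0.225, 0.683 and 0.0927) or single culture replicates 1, 2 or 3 (up to 0.739, 0.308 and 0.432), that of the cell cycle also after quantile normalisation (0.0583). Without 1 array the medians ranged from -0.37 (without single culture replicate 3) to -0.06 (without replicate 1) for NRF2 targets, from 0.06 (without single culture replicate 2) to 0.17 (without replicate 1) for the cell cycle, from -0.23 (without single culture replicate 1) to -0.11 (without 50% replicate 1) for p53 targets, and down to -0.81 for immediate early genes (without single culture replicate 3).

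**Figure D3:**
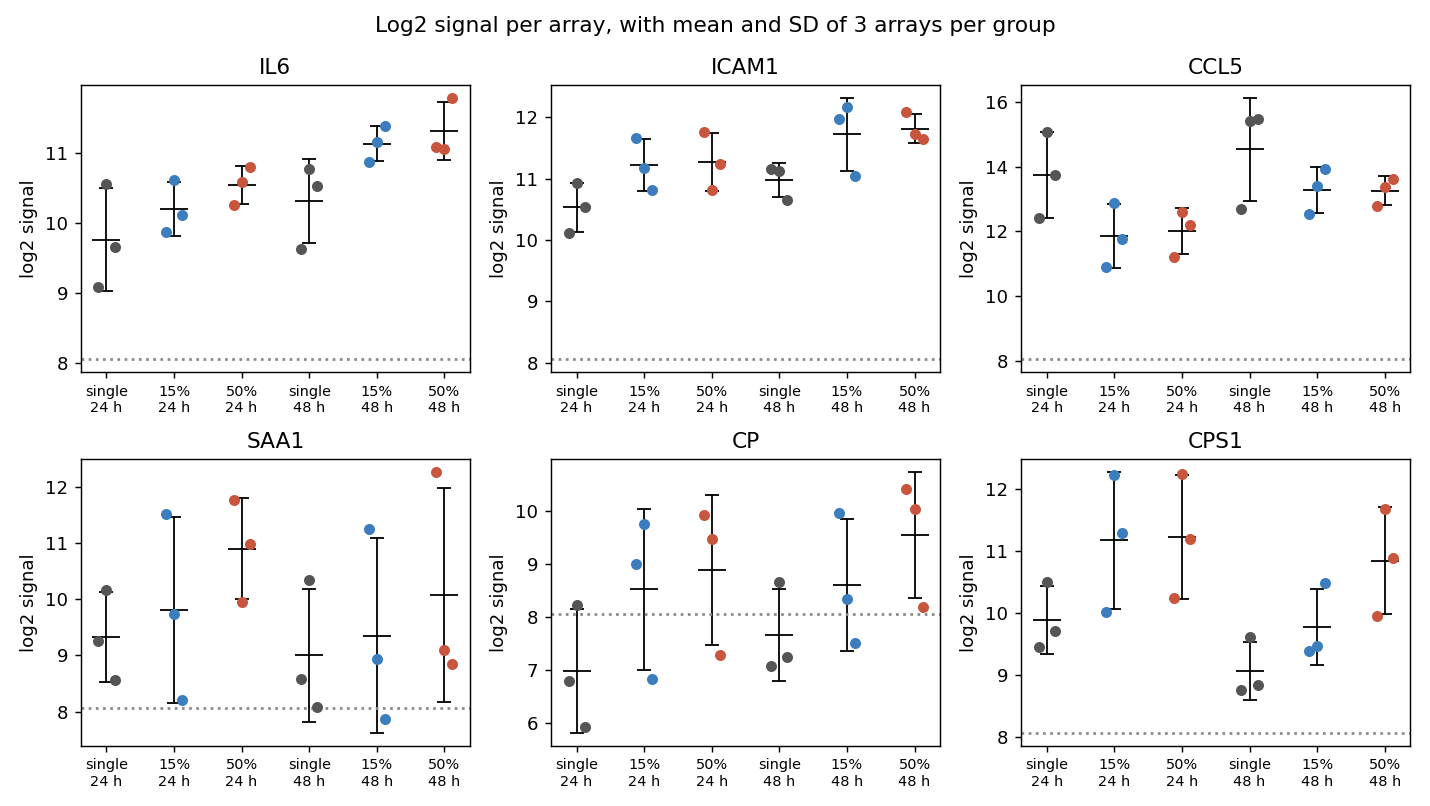
Points give the log2 signal of IL6, ICAM1, CCL5, SAA1, CP and CPS1 on each array, with bars for the mean ± SD of the 3 arrays of a group and a dotted line at 8.06, the median background level. IL6 lay above that line on every array, while CP crossed it within groups.

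For 15% co-culture at 48 h, IL6 differed from single culture by 0.83 ± 0.34 (SE, n = 3 per group), 1.77-fold, or by 0.49 without single culture replicate 1. ICAM1 differed by 0.75 ± 0.30. Metallothioneins were higher for 9 of 11 members (median 0.53, adjusted p = 0.000501), with MT1G at 0.59 ± 0.30. Cholesterol synthesis genes were higher for 17 of 19 (median 0.23, adjusted p = 0.00171), with SQLE, the squalene epoxidase, at 0.48 ± 0.29, and NF-kappaB target genes for 17 of 21 (median 0.21, adjusted p = 0.00324). Cytokines and chemokines were higher for 20 of 30 (median 0.14, adjusted p = 0.0466), and type I interferon response genes lower for 31 of 36 (median -0.24, adjusted p = 0.00909). These were the 5 lists that passed, each with adjusted p = 0.995 with an estimated correlation. MMP2, a matrix protease, differed by 1.01 ± 0.44 and CCL5 by -1.24 ± 0.69. Limma called 0 clusters (smallest adjusted p = 0.9999), with 612 at an unadjusted p under 0.05 and 0 adjusted over the list alone. With the block for runs of sample numbers it called 1. Without 15% replicate 2 the calls of metallothioneins, cholesterol synthesis, NF-kappaB targets and cytokines ended (adjusted p = 0.354, 0.853, 0.41 and 0.0892), the first 3 at medians of 0.22, 0.02 and 0.06 against 0.78, 0.41 and 0.34 without 15% replicate 3, and without 15% replicate 1 those of type I interferon and cytokines (0.763 and 0.396). The interferon median was -0.65 without single culture replicate 1, 0.0051 without replicate 2 (adjusted p = 0.944) and -0.02 without replicate 3 (0.96), which also ended the metallothionein call (0.0932). Cytokines did not pass without single culture replicates 1 or 3 (0.411 and 0.0932), without 15% replicate 3 of 24 h (0.0646), after quantile normalisation (0.053) or without the dimmest clusters (0.389).

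The lists of cytochrome P450 enzymes, the urea cycle, hepatic transporters, plasma proteins and liver transcription factors did not pass in any of these 4 comparisons (smallest camera adjusted p = 0.112), nor did 4 lists of markers of other cell types. The IL-6 and STAT3 response list did not pass in any of them either, although IL6 itself was higher. Its median at 24 h was 0.07 in 50% co-culture (-9.2e-05 without 50% replicate 2) and 4e-04 in 15% co-culture. Albumin (ALB), the main plasma protein of hepatocytes, differed by -0.01 ± 0.98 (SE, n = 3 per group) in 50% co-culture at 24 h and 0.05 ± 0.98 at 48 h, and by -0.24 ± 0.98 and -0.44 ± 0.98 in 15% co-culture. CYP3A4 and CYP1A2, drug metabolising enzymes, and CRP, an acute phase marker, lay below background in both cultures in each comparison. Of 33 measured macrophage markers, 2 were above background on at least 3 of the 6 arrays of 50% co-culture and single culture at 24 h. Their median change was 0.07 there (camera adjusted p = 0.0957), and ran from -0.01 without 50% replicate 2 to 0.15 without 50% replicate 3. It was 0.03 in 15% co-culture at 24 h, and 0.07 and -0.02 in 50% and 15% co-culture at 48 h. Lymphocyte and platelet markers had medians of -0.08, 0.03, 0.01 and -0.04 in the same order, bile duct and progenitor markers -0.04, 0.23 (0.03 without 15% replicate 3 and 0.36 without 15% replicate 2), 0.03 and -0.17, and endothelial and stellate markers 0.0044, -0.05, 0.03 and -0.03. The smallest adjusted p over these 3 lists was 0.446. KRT19, a keratin of bile duct cells, was 2.24-fold lower in 15% co-culture at 24 h (-1.16 ± 0.42), but differed by -0.49 without replicate 3 of that group, the array that stood apart.

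Further inflammatory reference genes differed from single culture by little beside their error or lay near background. NFKBIA, the inhibitor of NF-kappaB, differed by 0.38 ± 0.25 and 0.33 ± 0.25 (SE, n = 3 per group) in 50% and 15% co-culture at 24 h, and by -0.07 ± 0.25 and 0.27 ± 0.25 at 48 h. IL1B, a cytokine released by inflammasomes, differed by 0.24 ± 0.51 and 0.11 ± 0.51 at 24 h and by 0.30 ± 0.51 and 0.39 ± 0.51 at 48 h. CXCL8, a neutrophil chemokine, was above background on 1 co-culture array and on 0 single culture arrays in both comparisons at 24 h, and on 1 and 1 at 48 h. The monocyte chemokine CCL2, the feedback inhibitor SOCS3 and the nuclear receptor NR1I3 lay below background on all of these arrays.

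The share of macrophages was tested by setting 50% against 15% co-culture. At 48 h acute phase proteins were higher at 50% for 17 of 19 members (median 0.52, adjusted p = 0.000159), while metallothioneins were lower for 9 of 11 (median -0.54, adjusted p = 0.000124). NRF2 targets (median -0.31, adjusted p = 0.000159), immediate early genes (-0.42, adjusted p = 0.000947), cholesterol synthesis (-0.21, adjusted p = 0.00139) and NF-kappaB targets (-0.12, adjusted p = 0.0394) were lower at 50%, and cell cycle genes (0.12, adjusted p = 0.0211) higher. Each of these 7 lists had adjusted p = 0.665 with an estimated correlation. At 24 h all 14 ribosomal protein genes were higher at 50% (median 0.31, adjusted p = 0.000241, and adjusted p = 0.904 with an estimated correlation), and passed without each of the 6 arrays, at medians from 0.17 without 15% replicate 3 to 0.49 without 15% replicate 1. Limma called 0 clusters at 24 h and 0 at 48 h, with 985 and 475 at an unadjusted p under 0.05, and 0 genes adjusted over the list alone at either time. Without 15% replicate 2 of 48 h, only the acute phase call was left of the 7 lists of that time. The medians were then -0.28 for metallothioneins (adjusted p = 0.459), -0.13 for NRF2 targets (0.517), -0.13 for immediate early genes (0.632), 0.00015 for cholesterol synthesis (0.816), -0.06 for NF-kappaB targets (0.654) and -0.01 for the cell cycle (0.889). The acute phase median was 0.17 without 50% replicate 1 (adjusted p = 0.083), 0.28 without 15% replicate 3 and 0.84 without 15% replicate 1. Without 15% replicate 3 that of metallothioneins was -0.84, and without 15% replicate 1 that of the cell cycle was 0.24. Metallothioneins, NF-kappaB targets and the cell cycle did not pass without 50% replicate 3 (0.0714, 0.426 and 0.0637), nor NF-kappaB targets without 50% replicate 2 or 15% replicate 1 (0.147 and 0.0752).

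The change with time in the absence of macrophages was tested by setting single culture at 48 h against 24 h. S100A9, a calcium-binding antimicrobial protein, was 2.05 ± 0.57 log2 units higher at 48 h (SE, n = 3 per group; adjusted p = 0.022 over its list). CD55, which shields cells from complement, was 1.28 ± 0.35 higher (0.0388), OSMR, the oncostatin M receptor, 0.84 ± 0.23 (0.0158), IL4R 0.80 ± 0.19 (0.00911), IFI16, a sensor of DNA, 0.65 ± 0.20 (0.0416) and the adhesion molecule PECAM1 1.45 ± 0.43 (0.0362). Adjusted over the list alone, 8 genes passed in limma, the others being CHI3L1 and ACTA2, above background on 0 and 1 of the 18 arrays. Over all genes the adjusted p of these 8 lay between 0.60 and 0.84. All 8 lost the call over the list alone without 24 h replicate 3 (adjusted p from 0.093 to 0.223). Without 48 h replicate 2, 7 lost it (up to 0.331), and at least 1 did without each of the other 4 arrays (up to 0.23). With the block for runs of sample numbers limma called 2 clusters over all genes. Without it limma called 0 (smallest adjusted p = 0.255), with 1039 at an unadjusted p under 0.05. PAQR5 (0.99 ± 0.19), LRP8 (0.84 ± 0.16) and MPP1 (-0.87 ± 0.17), chosen after their values were seen, shared that smallest adjusted p with CD52, which was above background on 6 of 18 arrays and was also chosen after its values were seen.

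Immediate early genes were higher at 48 h for 16 of 17 members in single culture (median 0.58, adjusted p = 1.21e-05), but their median was 0.13 without 48 h replicate 1 (adjusted p = 0.461). NF-kappaB targets were higher for 18 of 21 (median 0.27, adjusted p = 0.000644), whereas cell cycle genes were lower for 25 of 32 (median -0.16, adjusted p = 0.000644, and a median of -0.08 without 48 h replicate 2), and both passed without each of the 6 arrays. Antimicrobial genes (median 0.34, adjusted p = 0.00168), the IL-6 and STAT3 response (0.26, adjusted p = 0.005) and 5 further lists passed as higher: acute phase proteins (0.36), hypoxia response (0.26), cytokines (0.21), cholesterol synthesis (0.19), each with adjusted p = 0.0159, and the unfolded protein response (0.21, adjusted p = 0.023). Heat shock genes were lower (-0.26, adjusted p = 0.0257) and complement components higher (0.13, adjusted p = 0.04997). With an estimated correlation these 12 lists had adjusted p between 0.352 and 0.69. The acute phase median was -0.05 without 48 h replicate 2 (adjusted p = 0.531) and 0.15 without 24 h replicate 3 (0.288). Without 1 array the hypoxia median ranged from 0.10 (48 h replicate 1) to 0.41 (24 h replicate 2), and medians were -0.01 for heat shock genes (24 h replicate 1), 0.13 for the unfolded protein response and for the IL-6 and STAT3 response and 0.23 for complement components (48 h replicate 1), 0.22 for antimicrobial genes (48 h replicate 2) and 0.31 for cholesterol synthesis (24 h replicate 3). The other 8 lists each lost their call without at least 1 array, with adjusted p up to 0.479, 0.403 and 0.428 without 24 h replicates 1, 2 and 3 and up to 0.328, 0.743 and 0.343 without 48 h replicates 1, 2 and 3.

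Averaged over both times, the 50% co-cultures were compared with the single cultures to draw on 12 arrays. IL6 was 0.89 ± 0.24 log2 units higher (SE; adjusted p = 0.041 over its list), CXCL5 0.97 ± 0.28 (0.0414), ICAM1 0.79 ± 0.21 (0.033), CPS1 1.56 ± 0.38 (0.0128) and TGFBI 0.97 ± 0.26 (0.0233). Adjusted over the list alone, 7 genes passed in limma, the others being KLF2, lower and above background on 4 of 18 arrays (adjusted p = 0.00572), and the protease MMP12, below background on every array. KLF2 passed without each of the 12 arrays, whereas CPS1 did not without 50% replicate 2 of 24 h or of 48 h (adjusted p = 0.0552 and 0.0562). IL6, CXCL5, ICAM1, TGFBI and MMP12 did not pass without 5, 7, 7, 6 and 10 of the 12 arrays (up to 0.17). Over all genes limma called 0 clusters (smallest adjusted p = 0.111), with 877 at an unadjusted p under 0.05. There IL6, ICAM1, CPS1, TGFBI and KLF2 had adjusted p between 0.60 and 0.82, and CXCL5 and MMP12 higher values still. TFPI2, an inhibitor of coagulation proteases chosen after its values were seen, differed by 0.87 ± 0.17 (adjusted p = 0.305). PDE4D, also chosen after its values were seen, had the smallest adjusted p and was above background on 3 of 18 arrays. Without 50% replicate 1 of 24 h it was the 1 cluster called (adjusted p = 0.0252). With a block for runs of 6 consecutive sample numbers, which the labels do not state as a pairing, limma called 18 clusters. TFPI2 and PDE4D were among them (adjusted p = 0.0297 and 0.0102).

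The camera test called 11 lists for the mean of both times. Hypoxia response genes were higher for 19 of 19 members (median 0.53, adjusted p = 1e-09, and adjusted p = 0.527 with an estimated correlation), acute phase proteins for 17 of 19 (0.49, adjusted p = 4.45e-07) and cytokines for 23 of 30 (0.15, adjusted p = 0.000222). The latter 2 lists had adjusted p = 0.197 with an estimated correlation. Type I interferon response genes were lower for 34 of 36 members (-0.28, adjusted p = 5.92e-06) and immediate early genes for 14 of 17 (-0.35, adjusted p = 7.4e-06). Complement components (0.11, adjusted p = 0.00278), the interferon-gamma response (0.13, adjusted p = 0.00591), NF-kappaB targets (0.15, adjusted p = 0.00681) and lipogenesis (0.11, adjusted p = 0.0183) were higher, and NRF2 targets (-0.14, adjusted p = 0.0175) and p53 targets (-0.16, adjusted p = 0.0188) lower. These 8 lists had adjusted p between 0.527 and 0.633 with an estimated correlation. Without single culture replicate 1 of 48 h the immediate early median was -0.17 (adjusted p = 0.0633), and complement components, the interferon-gamma response and NRF2 targets had medians of 0.01, 0.02 and -0.01 (0.0919, 0.509 and 0.328). NF-kappaB targets, lipogenesis and p53 targets lost their calls without 2, 3 and 6 of the 12 arrays (up to 0.12, 0.132 and 0.158), NF-kappaB targets at a median of 0.08 without 50% replicate 1 of 48 h. The hypoxia, acute phase, cytokine and type I interferon lists passed without each array, the acute phase at 0.31 without 50% replicate 2 of 48 h and the interferon list from -0.50 to -0.13 without single culture replicates 1 of 48 h and 2 of 24 h.

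Whether the response to macrophages differed between 48 h and 24 h was tested as a difference of effects. For 50% co-culture the hypoxia effect was smaller at 48 h in all 19 genes (median difference -0.56, adjusted p = 0.00868, and adjusted p = 0.927 with an estimated correlation). It was -0.21 without 50% replicate 2 of 24 h (adjusted p = 0.448), -0.17 without 50% replicate 3 of 48 h (0.485), -0.43 without single culture replicate 3 of 24 h (0.114) and -0.35 without single culture replicate 1 of 48 h (0.0515). For 15% co-culture the effect at 48 h was more positive for metallothioneins (0.73, 9 of 11 members, adjusted p = 0.00805), the unfolded protein response (0.34, 15 of 18, adjusted p = 0.0326) and NRF2 targets (0.30, 16 of 17, adjusted p = 0.0326). These 3 lists had adjusted p = 0.926 with an estimated correlation, and adjusted p of 0.192, 0.579 and 0.503 without 15% replicate 3 of 24 h. Without 15% replicate 2 of 48 h their medians were 0.44, 0.0089 and 0.05 (0.163, 0.848 and 0.737), and single culture arrays also ended these calls (up to 0.417). Camera called 6 other lists without 15% replicate 3 of 24 h, and 10 lists with a block for runs of 6 consecutive sample numbers. Limma called 0 clusters for 50% and 0 for 15%, with 326 and 638 at an unadjusted p under 0.05, and 0 genes adjusted over the list alone. For a single gene the median 95% interval of this difference reached 0.67 log2 units to either side.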

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

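The tests chosen only after their result was seen were those of a general shift, of macrophage RNA and of a deciding array behind the hypoxia list, the splits of the hypoxia list, the test of chance numbering, and, for the array that stands apart, the tests of less labelled sample and of a swapped label.

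The difference between the effects at the 2 times was tested for each co-culture, and 4 gene lists passed. The hypoxia response list had a median difference of -0.56 between the 50% co-culture effects at 48 h and 24 h. For 15% co-culture the median difference was 0.73 for metallothioneins, 0.34 for the unfolded protein response and 0.30 for NRF2 targets. None of the 4 passed with an estimated correlation, and each lost its call without at least 4 of the 12 arrays.

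The hypoxia response list was 0.84 log2 units higher in 50% co-culture at 24 h. A general shift of genes of this brightness was argued against, since the median lay at percentile 100 of 10000 matched random lists, and so was a single deciding array, as 0 of the 6 arrays ended the call. Macrophage RNA as the whole source was argued against too, though less clearly: the macrophage markers' median lay at percentile 95.6, with 18 of 33 higher. The abundant macrophage transcript LYZ had a mean of 3.21, far below background, and TYROBP exceeded background on 1 array. Both were chosen after their values were seen. CD68 and CTSS were above background on all 18 arrays, single cultures included, and SIGLEC1 on 3. SPP1 (0.87) and AIF1 (0.61) were higher in co-culture but below background on every array. Lower oxygen at the hepatocytes may have contributed: 23 of 24 further hypoxia genes were higher (median 0.46, percentile 100), with DDIT4 at 1.68 ± 0.72 and ALDOC at 1.42 ± 0.48, chosen after their values were seen, but the test shows that such genes move together and not that co-culture moved them. The 10 splits of the 6 arrays are too few for a share under 0.05: 2 gave a median as large, the real split at 0.84 and another at 0.95. That other split set both replicates 2 against both replicates 3, so it also held any difference between runs of sample numbers. Within each run the list level was higher in 50% co-culture than alone (0.57 against -0.56, 0.70 against -0.06 and -0.26 against -0.67). The labels state no pairing, so the splits leave co-culture and variation between arrays open.

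Replicate 3 of 15% co-culture at 24 h stood apart from the other 17 arrays. A swapped label was argued against, as 0 of 15 arrays of the other groups deviated as much from their group, and macrophage RNA was as well, the macrophage markers lying at percentile 62.2 of matched random lists. Less labelled sample on the array may be part of the source: 4 of 4 hybridisation controls lay above the range of the other arrays, with bioB at 9.74 against 8.32 to 8.89. Of 36 lists, the hypoxia response (-1.69), acute phase proteins (-0.93) and the interferon-gamma response (-0.72) deviated most from the other arrays of its group. Each lay at percentile 0 of random lists matched on brightness, so brightness alone does not account for them. Bile duct and progenitor markers deviated most the other way (0.42, percentile 94.3). Lower sample quality or a true difference in that culture stays open, and no biological explanation was tested.

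Arrays with neighbouring sample numbers deviated together from their group means. Their mean correlation within runs of 6 numbers was 0.188, against at most 0.142 in the other of 10000 assignments, so chance numbering was excluded at a share of 1e-04, the smallest they can give. A shared culture, donor, day or processing batch could each produce this, and the labels name none of them.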

How the results depend on the processing

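The fits without replicate 3 of 15% co-culture at 24 h, alone or with the block, the block with an estimated correlation, and the omission of single arrays for lists outside the 4 comparisons with single culture were chosen after seeing the data. The 4 comparisons of co-culture with single culture called 0 clusters by limma (531 and 1195 at an unadjusted p under 0.05 for 50% and 15% at 24 h, 616 and 612 at 48 h). Of 155 counts of clusters under all alternatives 146 stayed the same and 9 moved. Every main count was 0, so the same means 0 again, and the fold threshold could give nothing else. The counts that moved came from the block for runs and from 1 omission of an array. The samples are not paired by the labels. As a hint from the data, not the design, 35 of 45 pairs of arrays in the same run of 6 sample numbers had residuals that correlated over 0.1, against 4 of 90 pairs in different runs and groups, and among arrays of other groups, 18 of 18 arrays correlated best with one of their own run. With that run as a block, the counts were 2 for 50% and 1 for 15% co-culture at 48 h, 2 for time in single culture, and 18 for the mean of both times in 50% co-culture; with the block and without replicate 3 of 15% co-culture at 24 h they were 5, 2, 26 and 49. The clusters called with the block were among these, 2, 1, 2 and 18 of them. IGF2, chosen after its values were seen, was among those called at 48 h, and PDE4D, TFPI2, CPS1, CP, KLF2 and CCL5 were among the 18. Leaving out 1 array in turn gave 0 to 1 cluster for the mean of both times (PDE4D, without 50% replicate 1 of 24 h) and 0 elsewhere.

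The lists called for 50% and 15% co-culture numbered 12 and 8 at 24 h and 7 and 5 at 48 h. With an estimated correlation, with fry, and with the block and an estimated correlation together, each of the 4 counts was 0. Camera with an estimated correlation differs from the main test in how the correlation within a list is set. The list calls of the main test were not kept with an estimated correlation, and which part of that setting ended them was not tested. The estimated correlations themselves are not reported here, and why fry called 0 lists was not tested. Leaving out 1 array in turn gave 6 to 16, 3 to 11, 2 to 8 and 2 to 11 lists. For 15% at 24 h quantile normalisation gave 3 and the filter on dim clusters 5, the latter with fewer clusters tested. The type I interferon list in 50% co-culture at 48 h had a median of -0.20, which ranged from -0.543 to 0.0568 when 1 array was left out: it was 0.0286 without 50% replicate 1 and 0.0568 without single culture replicate 2, and at -0.0287 without single culture replicate 3 the test pointed up; the cause was not tested. Of 472 values of single lists, 282 stayed the same, 187 kept the direction of their test and no longer passed, and 3 reversed. Of 2356 values of single genes, 35 kept their direction and passed the threshold, and 2321 stayed without a call, 28 of them with a change of direction. Signal over background was the further limit, as 11530 of 21448 clusters were above background on no array.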

Other observations

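The tests of the splits of the cluster counts were chosen only after the result was seen; those of the splits of the list counts and of the shared direction were chosen before.

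The effect of 50% co-culture at 24 h resembled that at 48 h across clusters, with a Pearson correlation of 0.287. Genes are not independent replicates, so labels were exchanged within the runs of sample numbers instead. Of 64 exchanges 2 gave a correlation as high, the fewest possible, and the highest other was 0.227. The 3 other pairs of a 24 h and a 48 h effect had correlations of 0.152, 0.199 and 0.202, and 2 of 64 exchanges as high for each. A direction of change that persisted over both times is a candidate explanation, although the exchanges rest on runs that the labels do not state. By the same exchanges, the hypoxia list over both times was higher in 6 of 6 comparisons within a run (median 0.53, exact p = 0.0312, the smallest possible). Acute phase proteins (median 0.49) and coagulation factors (median 0.13) had the same exact p with 5 of 6 comparisons higher, and complement and negative acute phase proteins were also higher in 6 of 6 (exact p = 0.312 for each). None of the 36 lists passed (adjusted p = 0.375 for the smallest). With so few exchanges a list could pass only if most of the lists shared the smallest exact p, so this adjustment cannot decide on a single list.

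Other splits of the arrays were compared with the real groups. For each of the 7 comparisons of 2 groups the 10 splits are too few for a share under 0.05. The real count of clusters was 0 in each, so that 10 of 10 splits gave as many whatever the data, and the highest other count was 1 for 50% against 15% co-culture at 24 h and 0 in the other 6 comparisons. For the differences of effects and for the mean of both times, the real count was 0 as well, so that 100 of 100 splits gave as many, with a highest other of 1 for 50%, 10 for 15% and 1 for the mean. With a real count of 0 these splits say nothing about chance. For the lists, 2 of 10 splits gave as many as the real 12 of 50% co-culture at 24 h (highest other 18), 4 gave as many as the 8 of 15% at 24 h (highest other 16), 6 as many as the 7 of 50% at 48 h (highest other 12), and 8 as many as the 5 of 15% at 48 h (highest other 13). The median over the other splits was 5 lists for each comparison at 24 h and 8 for each at 48 h. The real counts of 7 and 5 at 48 h were below that median, so they do not stand out from other groupings of the arrays. For the mean of both times 15 of 100 splits gave as many as the real 11, with a highest other of 19, so chance is not excluded there. The split with 10 clusters was in the comparison that includes the array that stands apart, and whether a structure of the samples gave that count was not tested.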
